A study of Mus musculus with 20 samples.

How the data were processed

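Expression was measured by array in 20 mouse samples, 10 of thymocytes and 10 of thymic tumours, from mice with intact Gfi1 (WT) or labelled Gfi1 KO. Per the labels, RNA was extracted with a Qiagen kit, copied and amplified with a NuGEN kit for small amounts of RNA, labelled with biotin and stained with a fluorescent streptavidin. The deposited table holds 182058 probe sets by 20 arrays, and its values, from 3.37 to 15.01, were read as log2 signal. Their log base, background correction, normalization and summary method are not given in the sources used here, and scale and centring therefore rest on the values alone. The median of an array over all probe sets lay between 9.08 and 9.27, and over genes between 8.32 and 8.44. A fold change holds only if the base is 2. The number of arrays per group, 2 or 3, limits the precision.

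Probe sets were named through the platform annotation in GEO, which can be old. Of the probe sets, 167016 name 1 gene, 3388 name several genes and 11654 list none, and only the first kind was used. They name 19607 genes, and 16932 of these symbols are current RefSeq symbols of assembly GRCm38.p6, which served for names alone. Trp53 and Bax are named by no probe set used here. The values of 1180 probe sets repeat those of an earlier one. A gene has a median of 6 probe sets. Each probe set was centred on its mean over the 20 arrays, a gene took the median of its probe sets on each array, and the mean of its probe set means was added back. A gene was tested if it lay above the 40th percentile of an array in at least 2 of the arrays in the fit.

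Per the labels, thymocytes were untreated (2 WT and 2 KO arrays) or irradiated (3 and 3). Tumours followed the mutagen ENU alone (3 and 3) or in Notch1 transgenic mice (2 and 2). Nothing states that the samples of a group come from separate mice, so p-values may measure only technical spread. Thymocyte comparisons were fitted on the 10 thymocyte arrays and tumour comparisons on the 10 tumour arrays, with 1 mean per group. WT ENU tumours against WT untreated thymocytes were fitted on all 20 arrays. There were 11 comparisons: KO against WT in each of the 4 settings and as the mean of both tumour types, irradiated against untreated in each genotype, Notch against ENU tumours, WT ENU tumours against WT untreated thymocytes, and the differences in the irradiation response between genotypes and in the KO effect between tumour types. Tests used limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. Tables were read with the R package data.table, version 1.17.8, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. A value written a ± b is a log2 difference and its standard error (SE), unless it is given as mean ± SD. A single value in parentheses after a gene is its log2 difference. The median SE over the genes tested ran from 0.1 (KO against WT in irradiated thymocytes) to 0.318 (difference in KO effect between tumour types).

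The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Gfi1 first, by its probe sets. It then takes up to 10 largest rises and 10 largest falls past an adjusted p of 0.05 whose groups of arrays do not overlap, or, for differences between responses, past that threshold alone. It adds up to 4 members with the smallest p in each list described. The p53 targets Cdkn1a, Mdm2, Bax, Bbc3, Pmaip1, Ccng1, Trp53inp1 and Fas are named in each KO or irradiation comparison, with Trp53, Gfi1b, Id2, Bcl2, Bcl2l1, Mcl1, Myc, Hes1, Dtx1 and Il7r. Predicted genes without a symbol of their own were counted and may be left unnamed. For all named top genes of a comparison between groups, every array of one group therefore lay on the same side of every array of the other.

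In each of the 11 comparisons 27 gene lists were tested. They hold p53 targets, pro-apoptotic and anti-apoptotic genes, caspases, DNA repair, proliferation, histones, Notch targets, targets of GFI1 described in blood cells, MYC targets with ribosome biogenesis, glycolysis, oxidative phosphorylation, T cell receptor signalling, T-cell leukaemia genes, interferon response, inflammation and immediate early genes. The others are markers of double-negative, double-positive and mature single-positive thymocytes, gamma delta T cells, NK and cytotoxic cells, B cells, macrophages and dendritic cells, granulocytes, erythroid cells with megakaryocytes, and thymic stroma. The test was camera in limma with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. It compares a list with the other genes. camera with an estimated correlation and fry, which asks whether a list moves on balance one way without comparing it with other genes, were run beside it. Members past the threshold were counted among all genes tested and adjusted over the list alone.

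The alternatives were a further quantile normalization, centring each array on its median, no filter on dim genes or one at the 60th percentile, the mean of all probe sets of a gene, only the brighter probe sets, all 20 arrays in one fit, only the groups compared, a mean-variance trend with a robust prior, array weights, the replicate number as a block, and leaving out each array in turn. A pseudocount does not apply to values read as log2. After seeing the data, a fit without KO Notch tumour 2 and KO ENU tumour 3 together and list tests without KO Notch tumour 2 were added, as were lists of liver plasma protein, fetal, adult red cell and embryonic globin genes. Il18r1 in tumours, Slc15a2, Alb, Afp, H19, Igf2bp3, Hbb-y and Hba-x outside the rule, Pdlim1 and H2-Bl in ENU tumours, and H2-Bl in the mean of both tumour types, were named after their values were seen.

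The procedure was tested on simulated differences. Of genes shifted by 1 log2 unit, it recovered 98% for KO against WT in untreated thymocytes (12407 genes), 100% in irradiated thymocytes (12415 genes), 53.1% in ENU tumours (13048 genes), 42% in Notch tumours (13030 genes) and 56.2% for the mean of both tumour types (13025 genes). For irradiation it recovered 96% in WT (12407 genes), 94% in KO (12397 genes) and 84% for the difference between them (12416 genes). It recovered 8.2% for the difference in KO effect between tumour types (13043 genes), 63.3% for Notch against ENU tumours (13008 genes) and 62% for WT ENU tumours against WT untreated thymocytes (13183 genes). Of the calls, 3.4% to 8.4% were false, most for the difference in irradiation response. In the untreated thymocyte simulation, camera called a list of 20 genes shifted by 0.5 and 0 of 26 unshifted ones. Lists whose members vary together were not simulated.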

Results

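Expression was measured in thymocytes, the developing T cells of the thymus, and in tumours derived from them, in C57BL/6 mice. Gfi1 encodes a zinc finger repressor of transcription that acts in blood stem cells, granulocyte precursors and T cells. The series asks what the loss of Gfi1 changes in irradiated and in tumour-derived thymocytes. Untreated thymocytes had 2 WT and 2 KO arrays, irradiated thymocytes 3 and 3, tumours induced by the alkylating mutagen ENU 3 and 3, and tumours of ENU-treated mice with a Notch1 transgene (Notch tumours) 2 and 2. Tumour mice carried a floxed Gfi1 gene without (WT) or with (KO) the Mx1-Cre recombinase. Once a tumour was seen by ultrasound they received pIpC, which switches on Mx1-Cre and is itself an inducer of interferon, and tumour cells were taken some weeks later. The radiation dose, the time after it and the allele of the thymocyte KO mice are not given in the sources used here. Values of 2 arrays of the same group correlated between 0.87 and 0.988 across all probe sets, lowest between KO Notch tumours 1 and 2.

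Gfi1 itself is covered by 8 probe sets, numbered here 1 to 8 in the order of their IDs on the array. In untreated KO thymocytes, probe set 2 fell by 6.31 on the log2 scale, from 11.95 ± 0.17 in WT to 5.64 ± 0.03 (mean ± SD, n = 2 each, limma adjusted p = 2.44e-07). Probe sets 3 and 4 fell there too, with differences of -2.84 ± 0.14 and -2.24 ± 0.22, while probe sets 1, 5 and 7 rose by 1.07 ± 0.16, 1.07 ± 0.15 and 1.20 ± 0.18. Irradiated KO thymocytes showed another pattern: probe sets 1 to 3 rose (1.37 ± 0.13, 1.23 ± 0.12 and 0.98 ± 0.11) and probe sets 4 to 8 fell, with differences from -1.35 ± 0.18 to -2.44 ± 0.18 (limma adjusted p from 1.9e-05 to 0.00722). In KO Notch tumours, probe set 2 fell from 11.22 ± 0.30 to 6.70 ± 0.56 (mean ± SD, n = 2 each, limma adjusted p = 0.034), and probe set 3 had a difference of -1.67 ± 0.28 that did not pass (limma adjusted p = 0.259). In ENU tumours labelled Gfi1 KO, the 8 differences lay between -0.65 and 0.11 and 0 passed in limma (smallest adjusted p = 0.391), with probe set 2 at 10.85 ± 0.15 against 11.12 ± 0.50 in WT (mean ± SD, n = 3 each). The probe sets thus do not show the loss that the label states for the ENU tumours, which are called labelled Gfi1 KO throughout. Which part of Gfi1 each probe set covers, and which part was removed, is not given in the sources used here.

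**Figure D1:**
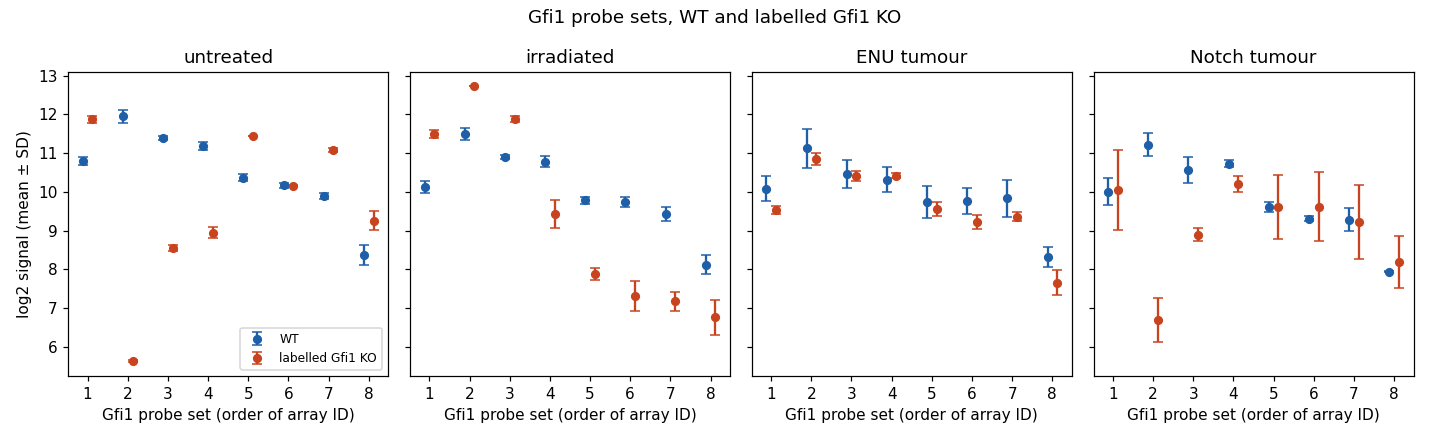
Log2 signal of the 8 Gfi1 probe sets, in the order of their IDs, in WT and labelled Gfi1 KO arrays of each setting, as mean and SD. Probe set 2 drops to 5.64 in untreated KO thymocytes and to 6.70 in KO Notch tumours, probe sets 4 to 8 drop in irradiated KO thymocytes, and WT and labelled KO ENU tumours lie close together.

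KO against WT in untreated thymocytes asks what the loss of Gfi1 changes before any treatment. Il18r1, a subunit of the receptor for interleukin 18, rose from 7.43 ± 0.01 to 11.68 ± 0.06 (mean ± SD, n = 2 each), a difference of 4.25 ± 0.11 (limma adjusted p = 3.41e-13). The other largest rises were Cd163l1, a scavenger receptor of gamma delta T cells (4.04 ± 0.18), the transcription factor Maf (3.36 ± 0.12), Sertad4 (3.33 ± 0.11), Zbtb10 (3.21 ± 0.17), the ephrin receptor kinase Epha2 (3.19 ± 0.12), the phosphatase Cdc14b (3.01 ± 0.14), and the germ cell genes Msh4 (3.41 ± 0.15) and Zp1 (3.34 ± 0.14). Hbb-b1, an adult haemoglobin chain, rose as well (4.13 ± 0.26). The largest falls were genes of neutrophil granules and secreted neutrophil proteins: Ngp (-4.47 ± 0.18), Lcn2 (-4.24 ± 0.18), S100a8 (-3.56 ± 0.12), S100a9 (-2.84 ± 0.13), Mmp8 (-2.61 ± 0.14), Ltf (-2.57 ± 0.11) and Retnlg (-2.41 ± 0.12), followed by Tdrd5 (-2.17 ± 0.11), Dgkg (-1.86 ± 0.11) and Lonrf1 (-1.70 ± 0.14). For each of these 20 genes both KO arrays lay on one side of both WT arrays. In all, 866 of 12747 genes were higher and 700 lower in KO, 177 and 44 of them by over 2-fold. The count of 1566 became 859 without WT untreated 1, 845 without WT untreated 2, 716 without KO untreated 1 and 780 without KO untreated 2. With all 20 arrays in one fit, 115 genes passed, and Dgkg, Lonrf1, Retnlg, Sertad4 and Tdrd5 were no longer among them.

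Markers of several cell types differed. Of the granulocyte genes, 12 of 14 fell (13 adjusted over the list alone). Their median was -2.05 (camera adjusted p = 4.11e-28, 0.00256 with an estimated correlation). Of the gamma delta T cell genes, 5 of 6 rose (5 adjusted over the list alone), among them Cd163l1, Maf and the cytokine receptor chain Il23r (1.26). Their median of 1.87 had a camera adjusted p of 1.76e-11 (0.00463 with an estimated correlation). Of the genes of NK and cytotoxic cells, 8 of 16 rose (9 adjusted over the list alone), with the pore-forming protein Prf1 (1.38), the protease Gzma (0.83) and Il2rb (0.84) as examples. Their median was 0.44 (camera adjusted p = 1.58e-08, 0.106 with an estimated correlation). Of the macrophage and dendritic cell genes, 12 of 18 rose (14 and 1 fell adjusted over the list alone), among them Ctss (1.18), Msr1 (0.70) and Itgax (0.70). Their median of 0.56 had a camera adjusted p of 3.14e-08 (0.154 with an estimated correlation). Of the B-cell genes, 7 of 15 rose (9 adjusted over the list alone), including Fcer2a (1.03), Faim3 (0.82) and Bank1 (0.65), and of the thymic stroma genes, 4 of 16 rose (5 adjusted over the list alone), including the junction protein Cldn4 (1.34). Their medians were 0.35 and 0.12 (camera adjusted p = 1.62e-06 and 0.00973, 0.106 and 0.124 with an estimated correlation). Of the erythroid and megakaryocyte genes, 6 of 10 rose and 1 fell (6 and 1 adjusted over the list alone), with the platelet chemokines Ppbp (2.89) and Pf4 (1.04), Hbb-b1 and the haem synthesis enzyme Alas2 (1.84). Their median of 0.79 had a camera adjusted p of 3.14e-06 (0.0312 with an estimated correlation). Also higher in these arrays were the embryonic globins Hbb-y (3.00 ± 0.17) and Hba-x (1.04), the plasma proteins Alb (2.03 ± 0.19) and Afp (0.84), the 2 of 6 tested genes of a liver list that rose (0 of 4 without them), and Igf2bp3 (1.18), an RNA-binding protein of fetal tissues. Without WT untreated 1 or 2, S100a8, S100a9, Mmp8, Ltf and Retnlg were too dim to test. Without KO untreated 1 or 2 they stayed lower (S100a8 -3.63 to -3.49). Fewer macrophage, NK, B-cell and stroma genes passed without some of these arrays. The erythroid gene that fell was lost without WT untreated 1 or KO untreated 2.

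Genes of T cell development differed by stage. Of the genes of double-negative thymocytes, the earliest stage, 6 of 17 rose (8 adjusted over the list alone), including the Notch target Dtx1 (0.62) and the progenitor receptor Flt3 (0.60). Their median was 0.27 (camera adjusted p = 8.46e-05, 0.0312 with an estimated correlation). Of the genes of double-positive thymocytes, 1 of 20 rose and 7 fell (1 and 7 adjusted over the list alone): Cpa3 (-0.99), Mns1 (-0.81) and the DNA polymerase Dntt (-0.68) fell while St6gal1 (1.12) rose. Their median of -0.13 had a camera adjusted p of 0.00973 (0.437 with an estimated correlation). Of the genes of mature single-positive cells, 10 of 28 rose and 2 fell (12 and 3 adjusted over the list alone), with the integrin chain Itgb7 (1.13) and the transcription factors Foxo1 (1.18) and Runx3 (0.92) rising. Their median was 0.25 (camera adjusted p = 5.23e-05, 0.244 with an estimated correlation). Of the genes described as bound or repressed by GFI1 in blood cells, 10 of 23 rose and 1 fell (12 and 2 adjusted over the list alone), among them Irf4 (0.89), Id1 (0.71) and Sfpi1 (0.74). Their median of 0.31 had a camera adjusted p of 0.000188 (0.149 with an estimated correlation). Gfi1b and Il7r were called at 0.42 ± 0.11 (limma adjusted p = 0.0178) and 0.48 ± 0.12 (limma adjusted p = 0.0136). Leaving out any 1 of WT untreated 1, WT untreated 2, KO untreated 1 or KO untreated 2 ended both calls, with an adjusted p from 0.0565 to 0.19 for Gfi1b and from 0.0534 to 0.133 for Il7r. Of the Notch targets, 2 of 19 rose (1 adjusted over the list alone), and of the T-cell leukaemia genes, 3 of 26 rose (3 adjusted over the list alone). Their medians were 0.22 and 0.11 (camera adjusted p = 0.0176 and 0.0269, 0.244 and 0.59 with an estimated correlation). T cell receptor signalling was not called, with 1 of 22 rising and 1 falling (1 and 1 adjusted over the list alone). Their median of -0.04 had a camera adjusted p of 0.936. Without these 4 arrays in turn, 3, 2, 2 and 2 double-negative, 7, 6, 7 and 7 mature, 8, 4, 4 and 4 GFI1 target, 1, 1, 1 and 1 Notch target and 1, 0, 0 and 1 leukaemia genes rose, and 4, 6, 5 and 4 double-positive, 1, 0, 0 and 0 mature and 1, 0, 0 and 0 GFI1 target genes fell. Of the receptor signalling genes, 1, 0, 1 and 1 rose and 0 fell.

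Of the immediate early genes, 10 of 23 rose (10 adjusted over the list alone) in untreated KO thymocytes, led by Jun (2.04), a subunit of the AP-1 factor. Their median was 0.21 (camera adjusted p = 8.48e-06, 0.244 with an estimated correlation). Of the interferon response genes, 6 of 31 rose and 1 fell (13 and 2 adjusted over the list alone), with Ifit3 (0.87), Rtp4 (0.83) and Rsad2 (0.78) rising and Oasl2 (-0.88) falling. Their median of 0.26 had a camera adjusted p of 0.000506 (0.352 with an estimated correlation). Of the inflammation genes, 5 of 15 rose (7 adjusted over the list alone), for example the chemokine Cxcl9 (1.01), and of the glycolysis genes, 4 of 15 rose (4 adjusted over the list alone), with the pyruvate kinase Pkm2 (0.82). Their medians were 0.31 and 0.23 (camera adjusted p = 0.00617 and 0.00247, 0.154 and 0.244 with an estimated correlation). Of the mitosis and cell cycle genes, 3 of 39 fell (2 adjusted over the list alone), and of the DNA repair genes, 5 of 38 fell (5 adjusted over the list alone). Their medians were -0.17 and -0.11 (camera adjusted p = 0.000765 and 0.0187, 0.437 and 0.578 with an estimated correlation). Of the MYC target and ribosome biogenesis genes, 1 of 25 rose (0 adjusted over the list alone). Their median was 0.13 (camera adjusted p = 0.0369, 0.6 with an estimated correlation). Without WT untreated 1, WT untreated 2, KO untreated 1 and KO untreated 2 in turn, 7, 1, 1 and 5 immediate early, 2, 3, 1 and 3 inflammation and 2, 1, 1 and 1 glycolysis genes rose, 0, 1, 0 and 0 cell cycle and 0, 1, 0 and 0 DNA repair genes fell, and 0 MYC target genes rose. Myc (0.26), Hes1 (0.05) and Id2 (0.10) did not pass.

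Genes of the p53 pathway and of cell death were not called as groups in untreated KO thymocytes. Of the p53 targets, 3 of 42 rose and 3 fell (9 and 4 adjusted over the list alone), with the repair factor Ddb2 (-0.58) falling. Their median of 0.01 had a camera adjusted p of 0.782. Cdkn1a, the cell cycle inhibitor p21, was at 0.43 ± 0.14 (limma adjusted p = 0.0544), and Mdm2 (-0.21), Bbc3 (0.14), Pmaip1 (0.23), Ccng1 (0.06), Trp53inp1 (0.07), Fas (-0.12), Bcl2 (-0.13), Bcl2l1 (0.25) and Mcl1 (-0.10) did not pass. Of the pro-apoptotic genes, 1 of 12 fell (1 adjusted over the list alone), of the anti-apoptotic genes, 0 of 8 passed (0 adjusted over the list alone), and of the caspases, 1 of 9 rose (1 adjusted over the list alone), the riser being Casp4 (0.74). Their medians were -0.03, -0.07 and 0.07 (camera adjusted p = 0.936, 0.725 and 0.772). Of the histone genes, 0 of 16 passed (0 adjusted over the list alone), and of the genes of oxidative phosphorylation, 0 of 27 passed (0 adjusted over the list alone). Their medians were -0.05 and 0.02 (camera adjusted p = 0.96 and 0.772). Without WT untreated 1, WT untreated 2, KO untreated 1 and KO untreated 2 in turn, 1, 2, 1 and 1 p53 targets rose, and 1, 2, 2 and 1 p53 targets and 0, 1, 0 and 0 pro-apoptotic genes fell. In total camera called 20 of 27 lists, fry called 14, and 4 kept their call with an estimated correlation: granulocyte, gamma delta T cell, erythroid and double-negative genes.

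KO against WT in irradiated thymocytes asks what the loss of Gfi1 changes in cells exposed to radiation. In these KO arrays Gfi1 probe sets 4 to 8 were low, of which only probe set 4 also fell in untreated KO thymocytes, and at gene level Gfi1 (-1.31 ± 0.12) fell (limma adjusted p = 6.59e-07). Il18r1 was again the largest rise, at 4.64 ± 0.09 (limma adjusted p = 2.98e-15, all 3 KO arrays above all 3 WT arrays), followed by the peptide transporter Slc15a2 (4.54 ± 0.12). Cdc14b (3.64 ± 0.11), Cd163l1 (3.33 ± 0.15), Sertad4 (3.24 ± 0.09), the chromatin remodeller Chd7 (3.23 ± 0.10), Maf (3.16 ± 0.10), Epha2 (3.09 ± 0.10) and the adhesion protein Amica1 (2.99 ± 0.13) rose as well. The neutrophil genes Ngp (-3.0 ± 0.15) and Lcn2 (-2.17 ± 0.14) fell most, then Tdrd5 (-2.13 ± 0.09), Sqrdl (-1.86 ± 0.13), Dgkg (-1.74 ± 0.09), the calcium channel subunit Cacna1e (-1.67 ± 0.11), the junction protein Jup (-1.65 ± 0.10), the adhesion receptor Gpr56 (-1.55 ± 0.10) and Ly6d (-1.50 ± 0.14). Each of these top genes had groups of arrays that did not overlap. Of 12747 genes, 1035 were higher and 868 lower, 186 and 34 of them by over 2-fold, and 863 and 1109 without WT irradiated 1. Of the genes higher in untreated KO, 593 were also higher here, and 271 were lower in both. Calls in opposite directions numbered 10 (r = 0.7 across genes, which are not independent replicates, and no arrays shared). Both comparisons used the same spread per gene, which favours shared calls. With all 20 arrays in one fit, 148 genes passed, and Cacna1e, Dgkg, Gpr56, Jup, Lcn2, Ly6d, Sertad4 and Tdrd5 were no longer among them.

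**Figure D2:**
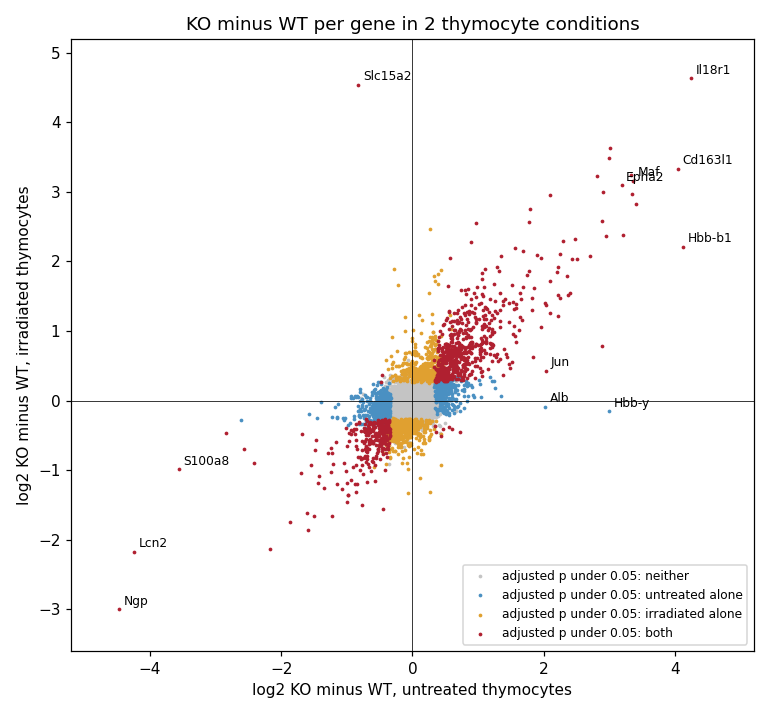
KO minus WT log2 difference of each tested gene in untreated (x axis) and irradiated (y axis) thymocytes, coloured by which of the comparisons had an adjusted p under 0.05. Most genes called in both lie along the diagonal, 593 higher in both and 271 lower in both.

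Of the granulocyte genes, 9 of 14 fell (12 adjusted over the list alone) in irradiated KO thymocytes, with S100a8 (-0.99) and Retnlg (-0.90) beside Ngp and Lcn2. Their median was -0.50 (camera adjusted p = 4.28e-09, 0.021 with an estimated correlation). Of the gamma delta T cell genes, 4 of 6 rose (4 adjusted over the list alone). Their median of 1.35 had a camera adjusted p of 2.99e-08 (0.0192 with an estimated correlation). Of the inflammation genes, 10 of 15 rose (12 adjusted over the list alone), among them the chemokines Ccl3 (1.71) and Cxcl2 (1.66) and the prostaglandin synthase Ptgs2 (1.0). Their median was 0.53 (camera adjusted p = 8.78e-11, 0.0192 with an estimated correlation). Of the macrophage and dendritic cell genes, 13 of 18 rose and 1 fell (14 and 1 adjusted over the list alone), with the lysozymes Lyz2 (2.06) and Lyz1 (1.79), Ctss (1.46) and H2-Aa (1.16) rising. Their median of 0.76 had a camera adjusted p of 9.09e-14 (0.103 with an estimated correlation). Of the NK and cytotoxic genes, 12 of 16 rose (12 and 1 fell adjusted over the list alone), for example Il2rb (0.95), Klrd1 (0.92) and Ctsw (0.86), and of the B-cell genes, 9 of 15 rose and 1 fell (10 and 1 adjusted over the list alone), with Cd79a (1.12) and Ms4a1 (0.74). Their medians were 0.52 and 0.44 (camera adjusted p = 2.99e-08 and 1.7e-06, 0.103 and 0.103 with an estimated correlation). The fall among B-cell genes was lost without WT irradiated 1 or KO irradiated 2. Of the erythroid and megakaryocyte genes, 4 of 10 rose and 1 fell (4 and 1 adjusted over the list alone), with Hbb-b1 (2.21) and Alas2 (0.63) rising. Their median of 0.21 had a camera adjusted p of 0.0034 (0.103 with an estimated correlation). The embryonic and liver transcripts of untreated KO thymocytes had other values here, Hbb-y (-0.15), Hba-x (0.05) and Alb (-0.09), none passing, and H19 (-1.12) fell.

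Markers of mature T cells went both ways in irradiated KO thymocytes, more of them up. Of the mature single-positive genes, 14 of 28 rose and 4 fell (16 and 6 adjusted over the list alone), including the transcription factor Klf2 (1.53) and its target S1pr1 (1.27), the receptor for thymus exit, with Cd53 (1.12) and H2-K1 (0.88). Their median was 0.35 (camera adjusted p = 5.44e-08, 0.158 with an estimated correlation). Id2, an inhibitor of E proteins, rose by 1.23 ± 0.11 (limma adjusted p = 4.33e-07) and Il7r (0.60) rose too. Of the interferon response genes, 16 of 31 rose and 1 fell (18 and 1 adjusted over the list alone), with Ifit3 (1.28) and Rtp4 (1.17) rising and Oasl2 (-1.20) falling. Their median of 0.30 had a camera adjusted p of 1.94e-07 (0.209 with an estimated correlation). Of the cell cycle genes, 14 of 39 fell (22 adjusted over the list alone), among them the nucleotide synthesis enzymes Tyms (-0.62), Tk1 (-0.49) and Rrm1 (-0.48). Their median was -0.29 (camera adjusted p = 2.48e-08, 0.234 with an estimated correlation). Of the p53 targets, 4 of 42 rose and 3 fell (4 and 3 adjusted over the list alone), and the list was not called. Their median of 0.05 had a camera adjusted p of 0.259. Without WT irradiated 2 and without KO irradiated 1, 4 and 8 cell cycle genes fell, 2 mature genes fell without WT irradiated 2 or KO irradiated 3, and 2 p53 targets rose without KO irradiated 1. Cdkn1a fell by 0.48 on the log2 scale (SE 0.11, limma adjusted p = 0.00712), while Mdm2 (0.01), Bbc3 (0.39), Ccng1 (0.13), Trp53inp1 (0.16), Fas (-0.17), Gfi1b (0.11), Bcl2 (0.03), Bcl2l1 (0.23), Mcl1 (0.16), Myc (0.23) and Hes1 (0.16) did not pass. Pmaip1 (0.47 ± 0.13, limma adjusted p = 0.0204) lost its call without 1 of WT irradiated 1, WT irradiated 3, KO irradiated 1 or KO irradiated 2 (highest adjusted p 0.0887). Dtx1 (0.34 ± 0.09, limma adjusted p = 0.0144) lost it without WT irradiated 3 or KO irradiated 1 (highest adjusted p 0.0744). camera and fry each called 14 of 27 lists, and the granulocyte, gamma delta T cell and inflammation lists kept their call with an estimated correlation.

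**Figure D3:**
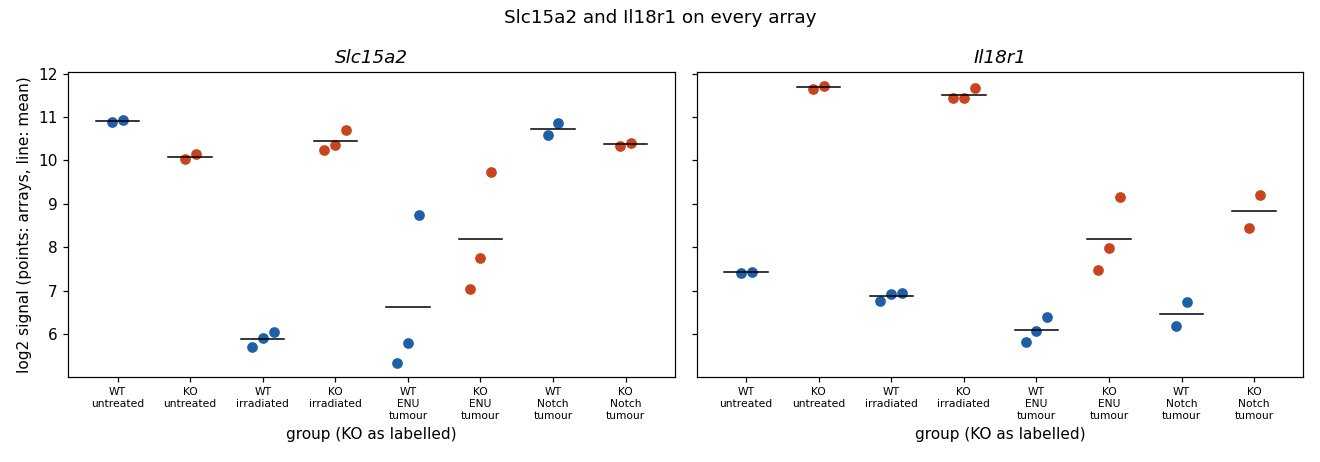
Log2 level of Slc15a2 and Il18r1 on each array by group, with a line at each group mean. Il18r1 is higher in every KO than in every WT thymocyte array, and Slc15a2 is low in WT irradiated thymocytes (mean 5.89) and in some ENU tumours.

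KO against WT in ENU tumours compares tumours labelled Gfi1 KO, whose Gfi1 probe sets show no loss, with WT tumours of the same origin. Interferon response genes were higher as a group in the tumours labelled Gfi1 KO, with 0 of 32 passing (22 rising adjusted over the list alone) and list mean levels of 9.95 ± 0.30 against 8.76 ± 0.17 in WT (SD, n = 3 each). Their median was 1.02 (camera adjusted p = 7.03e-25, 0.174 with an estimated correlation). The fry test called this list alone (adjusted p = 0.0367). Examples were Rtp4 (2.26 ± 0.31), Ifit1 (2.07 ± 0.32), Oas3 (1.94 ± 0.29) and Rsad2 (1.83 ± 0.25), none of which passed (limma adjusted p = 0.205 each). Genes of mature T cells also had a positive median, with 0 of 28 passing (7 rising and 1 falling adjusted over the list alone), for example S1pr1 (2.21 ± 0.38), Klf2 (1.64 ± 0.29) and Ccr7 (1.81 ± 0.42). Their median of 0.87 had a camera adjusted p of 1.23e-08 (0.174 with an estimated correlation). Of the NK and cytotoxic genes, 0 of 14 passed (4 rose adjusted over the list alone), of the erythroid and megakaryocyte genes, 0 of 9 passed (5 rose adjusted over the list alone), for example Hbb-b1 (2.67) and Ppbp (2.08), of the B-cell genes, 0 of 17 passed (0 adjusted over the list alone), and of the macrophage genes, 0 of 20 passed (0 adjusted over the list alone). Their medians were 1.24, 0.44, 0.96 and 0.61 (camera adjusted p = 1.45e-06, 0.00183, 0.00877 and 0.000176, 0.174, 0.236, 0.526 and 0.502 with an estimated correlation). Of the cell cycle genes, 0 of 39 passed (0 adjusted over the list alone), and of the MYC target and ribosome biogenesis genes, 0 of 26 passed (0 adjusted over the list alone). Their medians were -0.68 and -0.64 (camera adjusted p = 1.14e-07 and 7.71e-05, 0.502 and 0.502 with an estimated correlation). Of the p53 targets, 0 of 42 passed (0 adjusted over the list alone). Their median was -0.09 (camera adjusted p = 0.945). Cdkn1a was at -1.21 ± 0.79 and Il18r1 at 2.10 ± 0.42 (limma adjusted p = 0.438 and 0.284), and Mdm2 (-0.18), Bbc3 (0.39), Pmaip1 (0.45), Ccng1 (-0.09), Trp53inp1 (0.23), Fas (-0.27), Gfi1b (0.09), Id2 (0.30), Bcl2 (0.64), Bcl2l1 (-0.34), Mcl1 (0.17), Myc (-0.45), Hes1 (0.15), Dtx1 (-0.16), Il7r (1.0) and Gfi1 (-0.24) did not pass either. Among single genes limma called 0 of 13025 higher and 0 lower, with 1782 at an unadjusted p under 0.05 and a smallest adjusted p of 0.205. The count was 4 without WT ENU tumour 3. KO ENU tumour 3 was the one tumour array with signal of the Y-linked gene Kdm5d (9.71) and low Xist (6.27), with Eif2s3y, also Y-linked, at 6.99 against 10.32 to 11.45 in untreated thymocytes, and the other tumours had Xist between 12.63 and 13.54. camera called 17 of 27 lists and 0 with an estimated correlation.

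KO against WT in Notch tumours asks the same of tumours with a Notch1 transgene, where Gfi1 probe set 2 was lost. H2-Bl, a class I histocompatibility gene, was lower in KO (-2.04 ± 0.19, limma adjusted p = 0.0215), as was Pdlim1, a cytoskeletal adaptor (-1.89 ± 0.16, limma adjusted p = 0.0212). Both KO arrays lay below both WT arrays for each. They were the genes called by limma among 13025 (0 higher, 2 lower), with 780 at an unadjusted p under 0.05. Both calls were lost with array weights, with the replicate block, with only the groups compared, without WT Notch tumour 1 and without WT Notch tumour 2, where 0 genes passed (adjusted p of Pdlim1 up to 0.384 and of H2-Bl up to 0.402). The count rose to 1066, 506 higher and 560 lower, without KO Notch tumour 1 and was 5 without KO Notch tumour 2, and the further quantile normalization gave 4 higher and 6 lower. KO Notch tumour 2 had B-cell transcripts at high levels, Cd79a at 13.76 and Cd74 at 13.75, and lower T-cell ones, Cd8a at 8.96 and Rag1 at 7.86. Of the B-cell genes, 0 of 17 passed (0 adjusted over the list alone), for example Bank1 (3.05 ± 1.30) and Pou2af1 (2.65 ± 0.87), neither passing. Their median of 2.34 had a camera adjusted p of 9.41e-08 (0.459 with an estimated correlation). The camera adjusted p was 0.798 without KO Notch tumour 2. Of the interferon response genes, 0 of 32 passed (0 adjusted over the list alone), and of the cell cycle genes, 0 of 39 passed (0 adjusted over the list alone). Their medians were 0.55 and -0.44 (camera adjusted p = 1.02e-09 and 0.00022, 0.431 and 0.664 with an estimated correlation). Without KO Notch tumour 2 the interferon list stayed higher (camera adjusted p = 0.0108) and the cell cycle list turned to higher (0.0108). Of the p53 targets, 0 of 42 passed (0 adjusted over the list alone). Their median of 0.06 had a camera adjusted p of 0.181. Il18r1 was at 2.36 ± 0.51 (limma adjusted p = 0.389), and Cdkn1a (1.86), Mdm2 (0.04), Bbc3 (-0.08), Pmaip1 (0.60), Ccng1 (-0.08), Trp53inp1 (-0.44), Fas (0.33), Gfi1b (0.23), Id2 (-0.07), Bcl2 (0.04), Bcl2l1 (-0.32), Mcl1 (0.31), Myc (-0.42), Hes1 (-0.63), Dtx1 (0.11), Il7r (1.91) and Gfi1 (-0.12) did not pass either. camera called 13 of 27 lists, 0 with an estimated correlation, and fry 0.

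The mean of the KO effects in both tumour types asks what the tumours labelled KO share. Pdlim1 (-1.18 ± 0.10) and H2-Bl (-1.24 ± 0.12) were lower (limma adjusted p = 0.0277 and 0.0337), the calls among 13025 genes (0 higher, 2 lower), with 1430 at an unadjusted p under 0.05. The values in ENU tumours alone were smaller than in Notch tumours, -0.47 ± 0.13 and -0.45 ± 0.16, and did not pass (limma adjusted p = 0.347 and 0.352). Interferon response genes had a positive median, with 0 of 32 passing (22 rising adjusted over the list alone), for example Irf7 (1.74 ± 0.32), a factor that amplifies interferon signalling, Irf9 (1.01 ± 0.20) and Rsad2 (1.17 ± 0.20), none passing over all genes. Their median was 0.94 (camera adjusted p = 2.93e-27, 0.131 with an estimated correlation). Cdkn1a (0.33), Mdm2 (-0.07), Bbc3 (0.15), Pmaip1 (0.53), Ccng1 (-0.09), Trp53inp1 (-0.10), Fas (0.03), Gfi1b (0.16), Id2 (0.11), Bcl2 (0.34), Bcl2l1 (-0.33), Mcl1 (0.24), Myc (-0.43), Hes1 (-0.24), Dtx1 (-0.03), Il7r (1.45) and Gfi1 (-0.18) did not pass. Leaving out any 1 of the 6 ENU tumours or of WT Notch tumours 1 and 2 ended both calls, with an adjusted p up to 0.235 for Pdlim1 and 0.235 for H2-Bl, as did array weights and the replicate block. The count was 0 without WT ENU tumours 1 or 2, KO ENU tumours 2 or 3, or WT Notch tumours 1 or 2, 1 without KO ENU tumour 1, 1851 without KO Notch tumour 1 and 6 without KO Notch tumour 2. camera called 14 of 27 lists, 0 with an estimated correlation, and fry 0 (adjusted p = 0.051 for the interferon list).

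**Figure D4:**
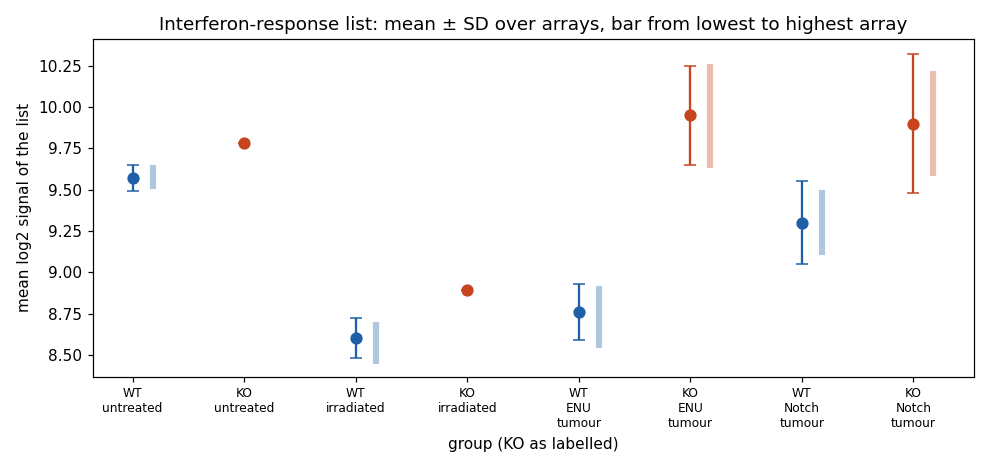
Mean log2 level of the interferon response list in each group, with points at the group mean ± SD and a bar from the lowest to the highest array. The mean is 8.76 in WT ENU tumours, 9.95 in labelled Gfi1 KO ENU tumours, 9.30 and 9.90 in WT and KO Notch tumours, and falls with irradiation in both genotypes of thymocytes.

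Irradiated against untreated WT thymocytes gives the response to radiation with Gfi1 present. Cdkn1a rose by 2.74 ± 0.13 (limma adjusted p = 5.39e-10, all 3 irradiated above both untreated arrays) and the p53 target Phlda3 (2.64 ± 0.14) by a similar size. The metal-binding protein Mt2 (2.79 ± 0.17), Mpzl2 (2.44 ± 0.12), the nucleotide receptor P2ry14 (2.13 ± 0.11), Lce1b (2.12 ± 0.40), Cecr2 (2.12 ± 0.11), Pde3b (2.09 ± 0.10), the amino acid transporter Slc38a3 (2.06 ± 0.13) and the Wnt pathway factor Tcf7l2 (2.05 ± 0.13) completed the largest rises. Slc15a2 fell most, from 10.91 ± 0.03 to 5.89 ± 0.17 (mean ± SD, n = 2 and 3), a difference of -5.01 ± 0.13. It was followed by the lysozymes Lyz2 (-2.82 ± 0.14) and Lyz1 (-2.42 ± 0.12), the interferon-induced genes Ifit3 (-2.69 ± 0.10) and Ifi205 (-2.07 ± 0.18), the neutrophil genes S100a8 (-2.45 ± 0.11) and Mmp8 (-2.08 ± 0.13), the small nucleolar RNA Snord118 (-2.50 ± 0.36) and the histone gene Hist1h2ac (-2.15 ± 0.12). Of 12747 genes, 1651 rose and 2762 fell, 94 and 241 by over 2-fold. The split depended on scaling, 2160 and 2284 after quantile normalization and 1344 and 2865 after centring. The count of 4413 was 2111 without WT untreated 1 and 548 with all 20 arrays in one fit, where Ifi205, Mpzl2, Mt2 and P2ry14 no longer passed.

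Of the p53 targets, 23 of 42 rose and 4 fell (23 and 6 adjusted over the list alone) with irradiation in WT, among them Sesn2 (2.03), Plk2 (1.94), the cell death gene Bbc3 (1.17) and Ccng1 (0.99). Their median of 0.43 had a camera adjusted p of 7.67e-08 (0.188 with an estimated correlation). Mdm2 (0.37 ± 0.11, limma adjusted p = 0.0122) lost its call without WT untreated 1 or 2 (highest adjusted p 0.107) and Pmaip1 (0.61 ± 0.15, limma adjusted p = 0.00433) without WT untreated 1 (adjusted p 0.078). Trp53inp1 (-0.08), Fas (-0.24), Bcl2l1 (-0.13), Gfi1b (0.14) and Il7r (-0.13) did not pass. Of the anti-apoptotic genes, 6 of 8 fell (6 adjusted over the list alone), including Bcl2 (-0.49), Mcl1 (-0.58), Cflar (-0.83) and Xiap (-0.83). Their median was -0.46 (camera adjusted p = 0.00358, 0.226 with an estimated correlation). Myc (-1.76), Id2 (-1.30) and Dtx1 (-0.87) fell and Hes1 (0.59) rose. At gene level Gfi1 fell (-0.50 ± 0.14, limma adjusted p = 0.0102), a call lost without WT untreated 1 or 2 (highest adjusted p 0.0627). Of the interferon response genes, 29 of 31 fell (30 adjusted over the list alone), such as Ifit1 (-2.01) and Usp18 (-2.01). Their median of -0.95 had a camera adjusted p of 2.69e-18 (0.159 with an estimated correlation). Of the macrophage genes, 15 of 18 fell (16 adjusted over the list alone), and of the granulocyte genes, 2 of 14 rose and 11 fell (2 and 11 adjusted over the list alone), with S100a9 (-2.06) and Ltf (-1.69) falling. Their medians were -0.84 and -1.20 (camera adjusted p = 1.76e-10 and 1.52e-08, 0.188 and 0.0742 with an estimated correlation). Cell cycle genes went both ways, with 16 of 39 rising and 11 falling (17 and 11 adjusted over the list alone), the mitotic kinases Aurka (-1.31) and Plk1 (-1.24) falling and the S phase genes E2f1 (0.96) and Cdc6 (1.19) rising. Their median of 0.05 had a camera adjusted p of 0.223. Without WT untreated 1 or 2, S100a8, S100a9, Mmp8 and Ltf were too dim to test. Fewer cell cycle genes fell without WT untreated 1, and fewer granulocyte genes rose without any 1 array. camera called 12 of 27 lists, fry 16, and 0 kept a call with an estimated correlation.

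Irradiated against untreated KO thymocytes is the same comparison, with the same limit, in cells labelled Gfi1 KO. In these, Gfi1 probe sets 2 to 4 had fallen in the untreated and 4 to 8 in the irradiated arrays. The largest rises were Mpzl2 (3.13 ± 0.12), Phlda3 (2.88 ± 0.14), Tcf7l2 (2.85 ± 0.13), Cecr2 (2.42 ± 0.11), Tceal1 (2.31 ± 0.11), P2ry14 (2.29 ± 0.11), the chemokine Cxcl2 (2.28 ± 0.15), the lipid enzyme Dgat1 (2.28 ± 0.10), Dmbt1 (2.20 ± 0.11) and Gch1 (2.12 ± 0.12). Falls were led by Hbb-y (-2.88 ± 0.15), with Hbb-b1 (-2.33 ± 0.24) and Alb (-2.01 ± 0.17) among the largest, all high in the untreated KO arrays. The others were Hist1h2ac (-2.69 ± 0.12), Snord118 (-2.60 ± 0.36), Ifit3 (-2.28 ± 0.10), the chemokine receptor Cxcr6 (-2.22 ± 0.11), Hsd11b1 (-2.08 ± 0.11), Cd226 (-1.99 ± 0.11) and Gfi1 itself (-2.07 ± 0.14). The fall of Gfi1 cannot be put down to radiation, as the lost probe sets differ. Sets 2 and 3 were at 5.64 and 8.55 untreated and 12.73 and 11.88 irradiated, with sets 5 to 8 lower there. Slc15a2, which fell most in WT, was at 0.35 ± 0.13 in KO. Of 12747 genes, 1925 rose and 3021 fell, 111 and 286 by over 2-fold (smallest limma adjusted p = 5.29e-11), a split of 2442 and 2526 after quantile normalization and 1636 and 3104 after centring. Of the risers in WT, 945 also rose in KO, and 2016 fell in both. Calls in opposite directions numbered 34 (r = 0.8 across genes, no arrays shared, same spread per gene). The count of 4946 was 2678 without KO untreated 1, 2875 without KO untreated 2, and 772 with all 20 arrays in one fit, where Hbb-b1 and Mpzl2 no longer passed. Alb lost its call with only the brighter probe sets.

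Of the p53 targets, 26 of 42 rose and 6 fell (26 and 6 adjusted over the list alone) with irradiation in KO, among them Cdkn1a (1.83), Plk2 (1.81), Sesn2 (1.61), Bbc3 (1.42), Ccng1 (1.07), Pmaip1 (0.84) and Mdm2 (0.60). Their median was 0.59 (camera adjusted p = 1.38e-08, 0.159 with an estimated correlation). The 6 falls were 3 without KO untreated 1, KO untreated 2 or KO irradiated 1. Myc (-1.79) and Dtx1 (-1.15) fell and Hes1 (0.70) rose, and Id2 (-0.16), Il7r (-0.01), Gfi1b (-0.17), Bcl2l1 (-0.15) and Trp53inp1 (0.01) did not pass. Fas (-0.29 ± 0.10), Mcl1 (-0.32 ± 0.11) and Bcl2 (-0.33 ± 0.10) passed (limma adjusted p = 0.0361, 0.0367 and 0.0191). Each lost its call without KO untreated 1, KO untreated 2 or KO irradiated 1, and Fas and Mcl1 also without KO irradiated 3 (highest adjusted p 0.249, 0.195 and 0.185). Of the interferon response genes, 29 of 31 fell (29 adjusted over the list alone), with Ifit1 (-1.99) and Usp18 (-1.87), and of the macrophage genes, 15 of 18 fell (16 adjusted over the list alone), with H2-Aa (-1.34). Their medians were -0.84 and -0.71 (camera adjusted p = 4.75e-15 and 5.42e-08, 0.159 and 0.262 with an estimated correlation). camera called 15 of 27 lists, fry 21, and 0 kept a call with an estimated correlation.

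**Figure D5:**
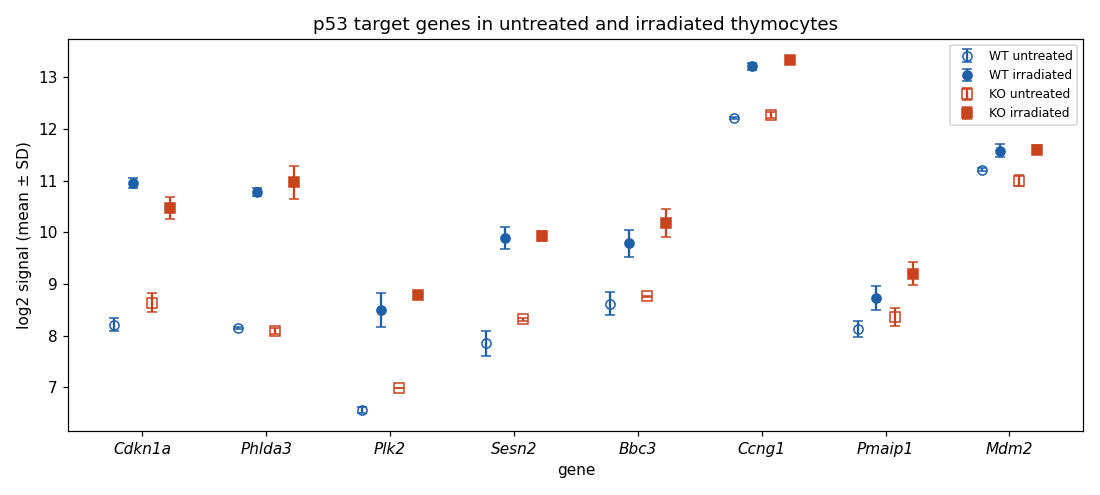
Log2 level of Cdkn1a, Phlda3, Plk2, Sesn2, Bbc3, Ccng1, Pmaip1 and Mdm2 in WT and KO thymocytes, untreated and irradiated, as mean and SD. All 8 are higher after irradiation in both genotypes, and Cdkn1a is lower in irradiated KO than in irradiated WT.

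The difference between the irradiation responses, KO minus WT, asks whether the response depends on genotype. It also carries every difference between the untreated and the irradiated KO mice, whose lost Gfi1 probe sets overlapped in probe set 4 alone and of which the untreated ones had higher erythroid transcripts and Alb. Slc15a2 differed most (5.36 ± 0.19, limma adjusted p = 2.14e-11), falling in WT and not in KO. Neutrophil genes were already low in untreated KO, where S100a8 was at 5.98 and after irradiation at 6.11 against 9.54 and 7.10 in WT. Their differences were S100a8 (2.57 ± 0.16), S100a9 (2.38 ± 0.17), Mmp8 (2.33 ± 0.18), Lcn2 (2.07 ± 0.23) and Ltf (1.87 ± 0.15). The immunoglobulin genes Igk (2.20 ± 0.29) and Igl-V2 (2.16 ± 0.25) and the chemokine Cxcl2 (1.88 ± 0.21) had a higher response in KO. Lower in KO were the responses of Hbb-y (-3.15 ± 0.22), Alb (-2.12 ± 0.24), Ppbp (-2.11 ± 0.17), Hbb-b1 (-1.92 ± 0.34), H19 (-1.24 ± 0.20), Jun (-1.61 ± 0.21), Gfi1 (-1.57 ± 0.20), the B-cell and dendritic cell factor Spib (-1.37 ± 0.19), Pls3 (-1.29 ± 0.15) and Slc38a3 (-1.26 ± 0.19). Alb lost this call with only the brighter probe sets, Hbb-b1 with the trend and robust prior, and Gfi1 with the mean of its probe sets. Id2, which fell in WT, differed by 1.13 ± 0.18 (limma adjusted p = 0.00234). Cdkn1a differed by -0.91 ± 0.18 (limma adjusted p = 0.0125), a call lost without WT untreated 1 or KO untreated 1 (highest adjusted p 0.136). Mdm2 (0.22), Bbc3 (0.25), Pmaip1 (0.24), Ccng1 (0.08), Fas (-0.05), Bcl2 (0.17), Mcl1 (0.26), Myc (-0.03), Trp53inp1 (0.09), Gfi1b (-0.31), Bcl2l1 (-0.02), Hes1 (0.11), Dtx1 (-0.27) and Il7r (0.12) did not pass. In all, 140 of 12747 genes had a higher and 100 a lower response in KO, a split of 105 and 138 without WT irradiated 1. The count of 240 was 88 without WT untreated 1, 89 without WT untreated 2, 61 without KO untreated 1, 92 without KO untreated 2 and 6 with all 20 arrays in one fit, where 14 of the 19 top genes no longer passed.

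Of 14 granulocyte genes, 11 had a higher and 1 a lower response in KO (12 and 1 adjusted over the list alone). Their median was 1.42 (camera adjusted p = 8.37e-29, 0.00238 with an estimated correlation). The erythroid and megakaryocyte list, with Alas2 (-1.20), had 0 higher and 4 lower of 10 (0 and 5 adjusted over the list alone), and the double-negative thymocyte list 0 and 1 of 17 (0 and 5). Their medians were -0.44 and -0.27 (camera adjusted p = 1.98e-05 and 0.000132, 0.038 and 0.038 with an estimated correlation). For the p53 targets the counts were 1 and 1 of 42 (1 and 1 adjusted over the list alone). Their median was 0.03 (camera adjusted p = 0.475). Without WT untreated 1 or 2, S100a8, S100a9, Mmp8 and Ltf were too dim to test, and the lower granulocyte response was lost. Without KO untreated 1, fewer erythroid genes had a lower response. The double-negative gene was lost without any 1 untreated array. Both p53 targets were lost without WT untreated 1 or KO untreated 1, and the higher one also without KO untreated 2. camera called 9 of 27 lists, fry 5, and the granulocyte, erythroid and double-negative lists kept their call with an estimated correlation.

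The difference in KO effect between Notch and ENU tumours asks whether the tumour type changes the effect. Interferon response genes such as Ifit1 (-2.08 ± 0.51), Rtp4 (-2.01 ± 0.50) and Oas3 (-1.89 ± 0.47) had negative differences, with 0 of 32 passing (3 falling adjusted over the list alone). Their median of -0.71 had a camera adjusted p of 2.18e-05 (0.657 with an estimated correlation). T cell receptor signalling genes such as Plcg1 (-1.42 ± 0.44) and Lcp2 (-0.96 ± 0.32) did too, with 0 of 22 passing (0 adjusted over the list alone), as did mature single-positive genes, with 0 of 28 passing (0 adjusted over the list alone). Their medians were -0.64 and -0.67 (camera adjusted p = 0.000126 and 0.000304, 0.135 and 0.657 with an estimated correlation). At single genes limma called 0 of 13025, with 934 at an unadjusted p under 0.05 and a smallest adjusted p of 0.114. The count was 1 without WT ENU tumour 2, 2 without WT ENU tumour 3, 261 without KO Notch tumour 1 and 2 without KO Notch tumour 2, and fry called 0 lists.

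Notch against ENU tumours, over both genotypes, asks what the Notch1 transgene adds. Cryba1, a crystallin of the lens, was higher in Notch tumours by 6.22 ± 0.32 (limma adjusted p = 0.000351), at 12.50 ± 0.51 in WT and 12.14 ± 1.31 in KO Notch tumours (mean ± SD, n = 2 each) against 5.99 to 6.23 on the 6 ENU tumour arrays. Ccnb1ip1 (1.46 ± 0.11), which acts in meiotic recombination, was higher, and the ectoenzyme Bst1 (-3.57 ± 0.32) and the vesicle protein Sytl1 (-1.13 ± 0.13) were lower (limma adjusted p = 0.00478, 0.011 and 0.041). These were the 4 genes called among 13025, with 1019 at an unadjusted p under 0.05. Ccnb1ip1 was lost without WT Notch tumour 1 (adjusted p = 0.0607), Bst1 without WT ENU tumours 1 or 2, KO ENU tumour 2 or WT Notch tumour 1 (highest 0.102), and Sytl1 without any 1 array except KO Notch tumour 1 (highest 0.179). The replicate block ended the calls of Ccnb1ip1 and Sytl1, and array weights, the stricter dim filter and the brighter probe sets that of Sytl1. The count was 2 without WT ENU tumours 1 or 2 or KO ENU tumour 2, 1 without WT Notch tumour 1, 557 without KO Notch tumour 1 and 12 without KO Notch tumour 2. Notch targets, 0 of 18 passing (0 adjusted over the list alone), were not called (median -0.07, camera adjusted p = 0.891), with Hes1 at -0.86 ± 0.52 and Notch3 at -0.89 ± 0.45 (limma adjusted p = 0.763 and 0.699). Gfi1 was at -0.16 ± 0.21. Of the cell cycle genes, 0 of 39 passed (0 adjusted over the list alone), and of the B-cell genes, 0 of 17 passed (0 adjusted over the list alone). Their medians were -0.35 and 0.91 (camera adjusted p = 2.66e-05 and 9.31e-05, 0.774 and 0.774 with an estimated correlation). Without KO Notch tumour 2 these became 0.591 and 0.687, the B-cell list with its direction turned. camera called 7 of 27 lists, fry 0, and 0 kept a call with an estimated correlation.

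WT ENU tumours against WT untreated thymocytes compares tumour and normal cells with Gfi1 intact. Effects of ENU, pIpC, the floxed Gfi1 gene and sex were not separated from those of the tumour. Xist was the largest rise (6.78 ± 1.37) and the Y-linked Eif2s3y (-5.92 ± 0.38), Uty (-4.79 ± 0.85) and Kdm5d (-4.03 ± 0.65) were among the largest falls, since all 10 thymocyte arrays carry Y-linked signal and the WT ENU tumours do not. The asparagine synthetase Asns (4.36 ± 0.64) rose (limma adjusted p = 0.000479, all 3 tumours above both thymocyte arrays), as did the growth factor receptor Pdgfrb (4.0 ± 0.81), Glp1r (3.86 ± 0.66), Bst1 (3.80 ± 0.36), the phosphatase Alpl (3.69 ± 0.61), Itga9 (3.66 ± 0.49) and Gfra1 (3.64 ± 0.63). A further pair of rises, Cym (4.76 ± 1.0) and Fbp1 (3.58 ± 1.07, limma adjusted p = 0.00455 and 0.0285), depended on single arrays. Falls were Ngp (-4.42 ± 0.46), Slc15a2 (-4.28 ± 0.79), Sgk3 (-4.18 ± 0.73), S100a10 (-4.08 ± 0.51) and Calcrl (-3.95 ± 0.60). Gfi1 was at -0.57 ± 0.25 (limma adjusted p = 0.121). Of 13520 genes, 1335 were higher and 1378 lower, 526 and 436 by over 2-fold, a split of 1187 and 1476 after quantile normalization and 1022 and 1606 after centring. The count of 2713 was 726 without WT untreated 1 and 909 without WT untreated 2. Cym lost its call without WT untreated 1 (adjusted p = 0.0582), and Fbp1 without WT untreated 1 or 2 or WT ENU tumours 2 or 3 (highest 0.162) and with the replicate block.

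Of the cell cycle genes, 17 of 39 rose (26 adjusted over the list alone) in the tumours, among them Mki67 (1.31), Foxm1 (1.43) and Plk1 (1.29). Their median was 0.89 (camera adjusted p = 9.89e-11, 0.41 with an estimated correlation). Of the MYC target and ribosome biogenesis genes, 13 of 26 rose (19 and 1 fell adjusted over the list alone), with Cad (2.0). Their median of 0.97 had a camera adjusted p of 2.66e-07 (0.447 with an estimated correlation). Of the mature single-positive genes, 1 of 29 rose and 18 fell (1 and 19 adjusted over the list alone), with Ms4a4b (-3.46), S1pr1 (-2.37) and Ccr7 (-2.31) falling. Their median was -1.03 (camera adjusted p = 1.74e-08, 0.119 with an estimated correlation). Of the granulocyte genes, 8 of 15 fell (9 adjusted over the list alone), with S100a8 (-3.50) and Ltf (-2.45), and of the interferon response genes, 1 of 32 rose and 18 fell (1 and 20 adjusted over the list alone), with Ifit1 (-2.46) and Ifi27l2a (-2.46) falling. Their medians were -1.43 and -0.74 (camera adjusted p = 9.89e-11 and 3.37e-08, 0.119 and 0.314 with an estimated correlation). Without WT untreated 1 or 2, S100a8, S100a9 and Ltf were too dim to test. Fewer cell cycle and MYC target genes then rose, and fewer mature and interferon genes fell. Without WT ENU tumour 1, 10 interferon genes fell, and without WT ENU tumour 3, 7 MYC target genes rose. camera called 11 of 27 lists, fry 13, and 0 kept a call with an estimated correlation.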

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

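Tests of other splits of the samples and of a variant under 1 Slc15a2 probe set were chosen before their results, and the other explanations below were tested only after the result was seen. A test of the difference between the irradiation responses of KO and WT thymocytes picked out 240 genes (88 without WT untreated 1, 89 without WT untreated 2, 61 without KO untreated 1, 92 without KO untreated 2). Higher in KO were Slc15a2 (5.36), S100a8 (2.57), S100a9 (2.38), Mmp8 (2.33), Igk (2.20), Igl-V2 (2.16), Lcn2 (2.07), Cxcl2 (1.88), Ltf (1.87) and Id2 (1.13). Lower were Hbb-y (-3.15), Alb (-2.12), Ppbp (-2.11), Hbb-b1 (-1.92), Jun (-1.61), Gfi1 (-1.57, but 0.18 with the mean of its probe sets), Spib (-1.37), Pls3 (-1.29), Slc38a3 (-1.26), H19 (-1.24) and Cdkn1a (-0.91, lost without WT untreated 1 or KO untreated 1). The neutrophil genes among them were already low in untreated KO, and whether background limits their fall was not tested. As lists, granulocyte (1.42), macrophage (0.28), anti-apoptotic (0.21) and inflammation genes (0.17) had a higher response, and erythroid (-0.44), gamma delta T cell (-0.35), double-negative (-0.27), glycolysis (-0.26) and MYC target genes (-0.15) a lower one. A test of the difference in KO effect between Notch and ENU tumours picked out the interferon (-0.71), mature single-positive (-0.67), T cell receptor (-0.64), oxidative phosphorylation (0.40) and MYC target (0.59) lists, 0 of them with an estimated correlation. Of these lists, granulocyte, erythroid and double-negative genes alone kept their call with an estimated correlation.

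No Gfi1 probe set is lost in ENU tumours labelled Gfi1 KO. Exchanged WT and KO labels are excluded only if deletion was full. The lowest WT ENU tumour lay 3.48 log2 units above the highest KO Notch tumour on probe set 2. Of 107 genes over 1 log2 unit higher in KO in both thymocyte comparisons, 93 were tested in tumours, and 66 of these had a positive change (median 0.38, 0.61 in Notch tumours, random sets between -0.19 and 0.01). Their mean level was 0.16 higher in the lowest tumour labelled KO than in the highest WT one, less than the SD of 0.22, so it stays open whether none of the cells lost Gfi1 function. Partial deletion may be another candidate and was not tested.

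Slc15a2 fell by 5.01 on the log2 scale in irradiated WT thymocytes, with arrays at 5.71 to 6.05 against 10.89 and 10.92. Radiation lowering it in either genotype is excluded, as it did not fall in KO (0.35, a call lost without KO untreated 1, KO untreated 2 or KO irradiated 2, adjusted p = 0.242, 0.102 and 0.156). A variant under a single probe set is excluded, as 15 of 18 probe sets were over 1 log2 unit lower. A heritable difference between the animals may be the source and stays open: 4 unirradiated arrays, all ENU tumours, lay within 2 log2 units of the irradiated WT arrays. A response to radiation that needs intact Gfi1 also stays open.

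Untreated KO thymocytes carried transcripts of embryonic globins and plasma proteins: Hbb-y and Alb were higher by 3.00 and 2.03, and Hbb-bh1, which was not tested, went from 5.38 to 7.53. RNA of adult liver stays open: without the members already seen, the liver list had a median of 0.15 (0 of 4 passing) and the fetal list 0.17 (0 of 5 passing). Loss of Gfi1 raising these genes stays open too: the whole liver list had a median of 0.31 in untreated and 0.01 in irradiated KO thymocytes, where the lost Gfi1 probe sets were not the same.

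Other splits of the same arrays were counted for each comparison of groups of 3 or more. For irradiated thymocytes 1 of 10 splits, the real one, called as many as 1903 genes and the highest other called 0, and 10 splits are too few for a share under 0.05. For ENU tumours every split (10 of 10, highest other 1) reaches the real count of 0 by construction, so the splits say nothing there. For the mean of both tumour types, 2 of 60 splits called as many as the real 2, a share under 0.05. The highest other called 3 and both calls are lost without any 1 of 8 of the 10 arrays, so chance is not excluded. For Notch against ENU tumours it was 4 of 100 (real 4, highest other 498), also a share under 0.05, but a split that calls 498 genes points to a structure of the samples, which was not tested.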

How the results depend on the processing

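Only 2 alternatives were chosen after the results were seen: leaving out KO Notch tumour 2 together with KO ENU tumour 3, and testing the lists without KO Notch tumour 2. Il18r1 stayed higher in KO in both thymocyte comparisons, and Ngp lower, under every alternative in which they were tested. Of the 95 named genes called in untreated KO thymocytes, 23 kept direction and call wherever tested. The corresponding numbers were 20 of 68 for irradiated KO thymocytes, 30 of 53 and 28 of 48 for irradiation in WT and KO, 4 of 34 for the difference between the irradiation responses, and 40 of 52 for ENU tumours against untreated thymocytes. For Notch tumours they were 0 of 2, for the mean of both tumour types 0 of 2, and for Notch against ENU tumours 1 of 4, Cryba1.

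Putting all 20 arrays in one fit moved every count it was run for by over 1.5 times. It gave 115 genes in untreated and 148 in irradiated thymocytes, 548 and 772 for irradiation in WT and KO, and 6 for their difference. Tumour comparisons moved the other way, to 679 in ENU tumours, 184 in Notch tumours, 347 for their mean, 126 for their difference and 329 for Notch against ENU. That fit shares 1 spread per gene between thymocytes, whose replicates were close, and tumours, whose replicates were not. Array weights gave 3518 genes in untreated thymocytes, 13 in ENU tumours, 1005 for the difference between the irradiation responses and 4950 for ENU tumours against thymocytes. They gave 0 in Notch tumours and 0 for the mean of both tumour types, where the block on replicate number gave 0 and 0 as well and 2 for Notch against ENU tumours. Fitting only the groups compared gave 3203 genes in untreated thymocytes and 0 in Notch tumours. Using only the brighter probe sets gave 935 and 1248 genes in untreated and irradiated thymocytes, 1 in Notch tumours, 1 for the mean of both, 103 for the difference between the irradiation responses and 2 for Notch against ENU tumours. Fewer genes were tested there. Other moves were 10 in Notch tumours after quantile normalization, 1 for the tumour difference without the dim filter, 2 for Notch against ENU tumours with the stricter one, and 0 for the mean of both tumour types without the pair of arrays named above. The cause of the moves with array weights, block and quantile normalization was not tested. Same-numbered arrays of different groups correlated between -0.41 and 0.09 after removing group means, so the numbers were not used to pair the samples.

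Leaving out 1 array gave 716 to 859 genes in untreated thymocytes and 1432 to 1972 in irradiated ones, 2111 to 5128 and 2678 to 4724 for irradiation in WT and KO, and 61 to 299 for their difference. The ranges were 0 to 4 in ENU tumours, 0 to 1066 in Notch tumours, 0 to 1851 for their mean, 0 to 261 for their difference, 1 to 557 for Notch against ENU tumours and 726 to 2465 for ENU tumours against thymocytes. In groups of 2 this leaves a lone array, which is assumed to vary like the other groups,. The highest counts in comparisons with Notch tumours came without KO Notch tumour 1, and the cause was not tested.

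The granulocyte and gamma delta T cell lists kept their call in both KO comparisons of thymocytes under each list test run. With an estimated correlation the lists called numbered 4 and 3 for untreated and irradiated KO thymocytes, 3 for the difference between the irradiation responses, and 0 each for ENU tumours, Notch tumours, their mean, irradiation in WT, irradiation in KO, the tumour difference, Notch against ENU tumours and ENU tumours against thymocytes. An estimated correlation widens the spread of lists whose members vary together. fry called 1 list in ENU tumours, 5 for the difference between the irradiation responses, and 0 in Notch tumours, for their mean, for the tumour difference and for Notch against ENU tumours. Without KO Notch tumour 2, camera called 6 lists in Notch tumours, 11 for the tumour difference and 1 for Notch against ENU tumours. There the B-cell list turned in Notch tumours (camera adjusted p = 0.798) and in Notch against ENU tumours (0.687), the cell cycle list turned in Notch tumours (0.0108), and the Notch target list turned in Notch against ENU tumours (0.358). The B-cell transcripts of that array are given in the report, and the cause of the other turns was not tested.

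Some called genes changed direction. With the brighter probe sets Ptgs2 and Sparc were at -0.25 and -0.57 in untreated KO thymocytes, and Blk and Ptgs2 at -0.01 and -0.74 in irradiated ones, none passing there (adjusted p = 0.887, 0.197, 0.977 and 0.398). Gfi1 in the difference between the irradiation responses was at 0.18 with probe-set means, since its probe sets move apart. Gfi1 at gene level in untreated KO thymocytes, not called at 0.26, was at -0.90 with probe-set means and passed there (adjusted p = 2.29e-05), for the same reason. The other turns were of values that had not passed, and their cause was not tested. In untreated thymocytes these were Ccng1 (-0.05) with probe-set means, Gfi1 (0.00), Hist1h1d (-0.07) and Hist1h2ae (-0.09) with the brighter probe sets, Bbc3 (-0.02 to 0.29), Hes1 (-0.05 to 0.16) and Hist1h2ae (-0.03 to 0.65) with 1 array left out. Irradiated thymocytes had Alb (0.01) and Bcl2 (-0.01) with probe-set means, Alb (0.10) and Fas (0.00) with the brighter probe sets, Mdm2 (-0.04) with array weights, Bcl2 (-0.03 to 0.10), Hba-x (-0.07 to 0.17) and Mdm2 (-0.06 to 0.06) with 1 array left out. For ENU tumours they were Ccng1 (-0.28 to 0.15), Dtx1 (-0.38 to 0.04), Hes1 (-0.01 to 0.38), Id2 (-0.03 to 0.52), Il7r (0.00 to 1.68), Mcl1 (-0.03 to 0.29) and Myc (-0.74 to 0.10) with 1 array left out. For Notch tumours they were Bbc3 (0.04) and Dtx1 (-0.05) with probe-set means, Bcl2 (-0.01) and Gfi1b (-0.03) with the brighter probe sets, Bbc3 (-0.20 to 0.05), Bcl2 (-0.23 to 0.31), Bcl2l1 (-0.95 to 0.32), Bub1 (-1.52 to 0.09), Ccng1 (-0.25 to 0.08), Dtx1 (-0.65 to 0.87), Fas (-0.90 to 1.56), Gfi1 (-0.69 to 0.44), Hes1 (-1.92 to 0.66), Id2 (-0.36 to 0.22), Mcl1 (-0.04 to 0.66), Mdm2 (-0.07 to 0.15) and Myc (-0.95 to 0.11) with 1 array left out. The mean of both tumour types had Dtx1 (0.00) and Mdm2 (0.01) after quantile normalization, Dtx1 (0.01), Fas (-0.07) and Mdm2 (0.00) with array weights, Dtx1 (0.17), Fas (-0.61), Gfi1 (0.11) and Hes1 (0.32) without KO Notch tumour 2 and KO ENU tumour 3 together, Id2 (0.00) with probe-set means, Ccng1 (-0.18 to 0.03), Cdkn1a (-0.16 to 0.66), Dtx1 (-0.40 to 0.35), Fas (-0.58 to 0.65), Gfi1 (-0.46 to 0.10), Hes1 (-0.88 to 0.41), Id2 (-0.05 to 0.26) and Mdm2 (-0.15 to 0.00) with 1 array left out. The irradiation response of KO had Gfi1b (0.25) and Il7r (0.00) with the brighter probe sets, Il7r (0.04) after quantile normalization, Trp53inp1 (-0.01) after centring, Trp53inp1 (-0.01) with probe-set means, Trp53inp1 (-0.01) with array weights, Il7r (-0.06 to 0.03) and Trp53inp1 (-0.04 to 0.06) with 1 array left out. Its difference from WT had Bcl2l1 (0.09) and Myc (0.01) with array weights, Fas (0.04) with probe-set means, Fas (0.12) with the brighter probe sets, Bcl2l1 (-0.09 to 0.05), Fas (-0.11 to 0.02) and Myc (-0.11 to 0.05) with 1 array left out. Notch against ENU tumours had Gfi1 (-0.44 to 0.12) with 1 array left out.

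As the values were read as log2 signal, no pseudocount was used. The background level of the arrays was not measured here. A transcript at it has a change that is a lower bound in size. Groups hold 2 or 3 arrays.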

Other observations

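These values were looked up only after the results were seen. Rag1, Cd8a, Cd8b1 and Cd3e were lower in KO Notch tumour 2 (7.86, 8.96, 8.77 and 12.38) than in KO Notch tumour 1 (12.29, 11.92, 11.51 and 13.76), while Cd79a and Cd74 were higher (13.76 and 13.75 against 9.55 and 10.30). Interferon response genes had mean levels of 9.57 ± 0.08 (SD) in WT untreated thymocytes, 9.78 in both KO untreated arrays, 8.60 ± 0.12 in WT irradiated thymocytes and 8.89 in all 3 KO irradiated arrays. Across 12346 genes, KO effects in thymocytes correlated with those in tumours between 0.24 and 0.35, and the tumour types with each other at 0.31 across 13025 genes, which are not independent replicates. Of the lists added after seeing the data, embryonic globins had a median of 2.02 in untreated and -0.05 in irradiated KO thymocytes and adult red cell genes 1.53 and 0.45, each list with members already seen.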
